A study of Rattus norvegicus with 6 samples.

How the data were processed

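Total RNA from the renal cortex of 6 rats was labelled with Cy3 and hybridised to 1 Agilent one-colour array per animal, per the labels' protocols. Scanner output was made with Agilent Feature Extraction, version 10.7.1.1 per the file headers and 10.7 per the submitters' processing notes. The main values are the deposited spot intensity after background subtraction and spatial detrending, on a linear scale, with no scaling between arrays, per the file headers. The median pixel intensity of each spot and of its local background, also per the file headers, served 1 alternative. A deposited table of the whole series holds linear values, each the ratio of a spot's processed signal to about the 75th percentile of its array. Set against the scanner values over 61537 probes, it had a constant ratio within each array and column medians of 0.110, 0.111, 0.114, 0.111, 0.108 and 0.112 for controls 1 to 3 and DPG 1 to 3. It is not centred per gene, and its direction matches the scanner signal; how the submitters scaled it is not given in the sources used here.

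Control spots were left out, and 0 spots were saturated. Log2 processed signal had each array's 75th percentile subtracted. A probe was kept where it was well above background on all 3 arrays of at least 1 group, which left 40406 probes, of which 23 with an outlier flag on any array were dropped. Probes were named through the accession of each probe, without versions, in a table of RefSeq genes of the assembly GRCr8. In all, 28206 probes matched 1 symbol each (15645 symbols), and 33331 kept the identifier of the file. The plan named probes by the gene name column, but the accession column was used because the scanner files hold accessions. No coordinates are given, since the arrays were designed on another assembly. For each gene the brightest kept probe stood for the gene, which gave 29647 features, 11912 of them with a gene symbol. Of 88 genes taken by the naming rule with several kept probes, 15 had log2 fold changes of both signs, and in 32 others the largest was over 1.5 times the smallest in size. The report gives the other probes for only some of these.

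Groups came from the labels. The DPG and control groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no trend), with Benjamini-Hochberg adjustment over all features at 0.05. The fit had 4 residual and 1.95 prior degrees of freedom. An exact permutation test of 3 against 3 cannot give a two-sided p below 0.1. Gene lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 32 lists. Beside it stood camera with an estimated correlation and fry, adjusted in the same way. Fry gave a directional test, meant wherever fry is named alone, and a mixed test that ignores direction. The lists held 649 genes, and 594 of the 673 entries had a tested feature. The mean shift of a list is the mean over its members of each array's log2 signal minus the control mean. Values written as a ± b are log2 fold changes, DPG over control, with the standard error from limma.

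The lists, main tests, groups, alternatives and rule for naming genes were fixed before the data were examined. Adjustment of genes over 1 list alone was not in that plan, and it is not corrected for the number of lists. The naming rule took up to 12 genes per direction by size among those past the adjusted threshold. It filled each direction to 12 by smallest p among symbols at least 1.5-fold apart. It added up to 4 members of each list by smallest p, and always Havcr1, Lcn2, Clu, Spp1, Timp1, Cyp2e1, Adh1 (current symbol Adh1c), Aldh2, Aldh1a1, Umod and Slc34a1. As no gene passed the adjusted threshold, the 24 leading genes came from the second part of the rule. A few genes that the rule takes are not reported here by name.

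The alternatives were normexp background correction (offset 50), median scaling, quantile normalization, no filter on dim probes, probes well above background on all 6 arrays, spots with outlier flags kept, the mean of a gene's probes, every probe on its own, an intensity trend with robust variance, array quality weights, the replicate number as a block, the deposited table, each animal left out in turn, and the other set tests. The normexp alternative was planned on the mean pixel signal and was run on the median pixel signal. A slide block could not be fitted, because each group lay on a slide of its own.

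The fit was tested on simulated data, drawn for the 29647 features from the real means and limma's moderated spreads, with 200 genes changed. At an adjusted p of 0.05 the comparison of DPG with control recovered 32% of genes changed 1.5-fold, 74% at 2-fold, 96% at 4-fold and 98% at 8-fold, with 9 false calls. These shares hold for the simulated spreads and changes only. In the real data Fst differed 9.31-fold and was not called (limma adjusted p = 0.204). In 20 simulations of independent genes with the cell cycle list shifted by 0.25 (log2), camera called that list in 20, and called 3 of 620 tests of lists without a shift. In the real arrays the estimated correlation of the cell cycle list was 0.15, against the preset 0.01. The simulations therefore do not give the rate of false calls for lists of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.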

Results

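Gene expression was measured in the renal cortex of 6 male Sprague-Dawley rats, with 1 one-colour Agilent array per animal. The cortex is the outer part of the kidney, which holds the glomeruli and most of the proximal tubule. The control group of 3 rats was given water, and 3 rats were given dipropylene glycol (DPG), a glycol solvent, at 1000 mg/kg/day, each for 4 weeks. Of the 61537 probes on each array, between 39556 (control 3) and 43184 (control 2) were well above background. The DPG arrays had 41524, 41663 and 41937 such probes. The number of arrays limits the precision of every value below. Control 3 stood apart from the other controls, with the fewest probes above background and 34 spots with outlier flags, against 0 in controls 1 and 2 and 4 in DPG 1. Pearson correlations across features between arrays lay between 0.991 and 0.993 within the control group, between 0.992 and 0.994 within the DPG group, and between 0.989 and 0.993 across the groups.

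The comparison asked which genes of the renal cortex differed between rats given DPG and rats given water. No single gene passed the adjusted threshold, while 5 of 32 gene lists fixed in advance did. Cell cycle genes and heat shock genes rose as lists in the DPG rats, with median log2 fold changes of 0.26 and 0.16 (adjusted p = 0.697 for each with an estimated correlation). Peroxisome proliferator-activated receptor alpha (PPAR-alpha) targets with fatty acid oxidation genes fell as a list, as did podocyte genes and collecting duct genes, with medians of -0.10, -0.17 and -0.16 (adjusted p = 0.812, 0.909 and 0.697 with an estimated correlation). These 5 calls came from camera with a preset correlation between genes. Other splits of the same arrays passed between 1 and 8 lists by this test, so the count of 5 does not set the real groups apart. None of the 32 lists passed with an estimated correlation, where the smallest adjusted p = 0.697.

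Across 29647 features, limma with Benjamini-Hochberg adjustment called 0 genes at an adjusted p of 0.05, and the smallest adjusted p = 0.125. At an unadjusted p of 0.05, 3669 features passed (12.4%), 1979 of them with higher and 1690 with lower signal in DPG, where chance gives 1482. At an unadjusted p of 0.01 together with a 1.5-fold difference, 338 features passed, 247 higher and 91 lower. That count was 198 with normexp background correction and 525 without DPG 3. The arrays of the groups did not overlap for 5831 features (19.7%), where chance gives 10%. Leaving out control 2 or DPG 2 brought the adjusted count to 1. The feature past the threshold was probe A_64_P009237 without control 2 and the transcript XM_344619 without DPG 2. Both were named after their values were seen.

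The 12 genes with the smallest p among those at least 1.5-fold higher in DPG were led in size by Fst, which encodes follistatin, a secreted binder of activins. Its log2 fold change was 3.22 ± 0.37 (SE, n = 3 per group), a 9.31-fold difference, with a limma adjusted p = 0.204. Its 3 probes gave log2 fold changes from 2.86 to 3.56, and the control arrays spread widely (SD 0.64). Nrn1l followed with 2.19 ± 0.19 (SE) and an adjusted p = 0.125 from limma. Prkab2, a regulatory subunit of AMP-activated protein kinase, had 1.47 ± 0.18, and Rexo5 had 1.27 ± 0.13. Pld1, a phospholipase D that makes phosphatidic acid, had 1.00 ± 0.13, with its 3 probes between 1.00 and 1.01. Csad, the decarboxylase that forms hypotaurine on the way to taurine, was measured at 0.98 ± 0.09, a 1.97-fold difference, and its DPG arrays varied by an SD of 0.02. The chromatin remodelling subunit gene Smarcd3 had 0.92 ± 0.08, the potassium channel subunit gene Kcns2 0.85 ± 0.09, and the mitochondrial carbonic anhydrase gene Car5b 0.78 ± 0.07. Cldn16, a tight junction claudin of the thick ascending limb needed for magnesium reabsorption, had 0.70 ± 0.06, and its second probe read 0.43. Hspb1, a small heat shock protein gene, also had 0.70 (SE 0.07), and Tinagl1 had 0.67 ± 0.08. The limma adjusted p of these genes lay between 0.125 and 0.211.

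The 12 genes chosen in the same way on the lower side differed by less. Dnajc5b had a log2 fold change of -1.29 ± 0.24 (SE, n = 3 per group), 2.45-fold lower in DPG. The complement component gene C8b had -0.90 ± 0.15, Plcxd2 -0.88 ± 0.07, Sez6l2 -0.86 ± 0.16 and the RNA exosome subunit gene Exosc3 -0.75 ± 0.09. All 4 probes of Plcxd2 lay between -1.25 and -0.85. Hrh4, a histamine receptor gene, had -0.70 ± 0.13, and its second probe read 0.04. Slc7a4 had -0.63 ± 0.11, and its second probe read 0.24. Sgcz had -0.70 ± 0.13, the secreted carbonic anhydrase gene Car6 -0.68 ± 0.11 (its 3 probes from -0.72 to -0.38), and the secretin receptor gene Sctr, well above background on 2 of 3 DPG arrays, -0.66 ± 0.13. The Toll-like receptor gene Tlr12 had -0.59 ± 0.12. The limma adjusted p of the lower genes lay between 0.125 and 0.244, and the 3 arrays of each group did not overlap for any of the 24 genes.

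**Figure D1:**
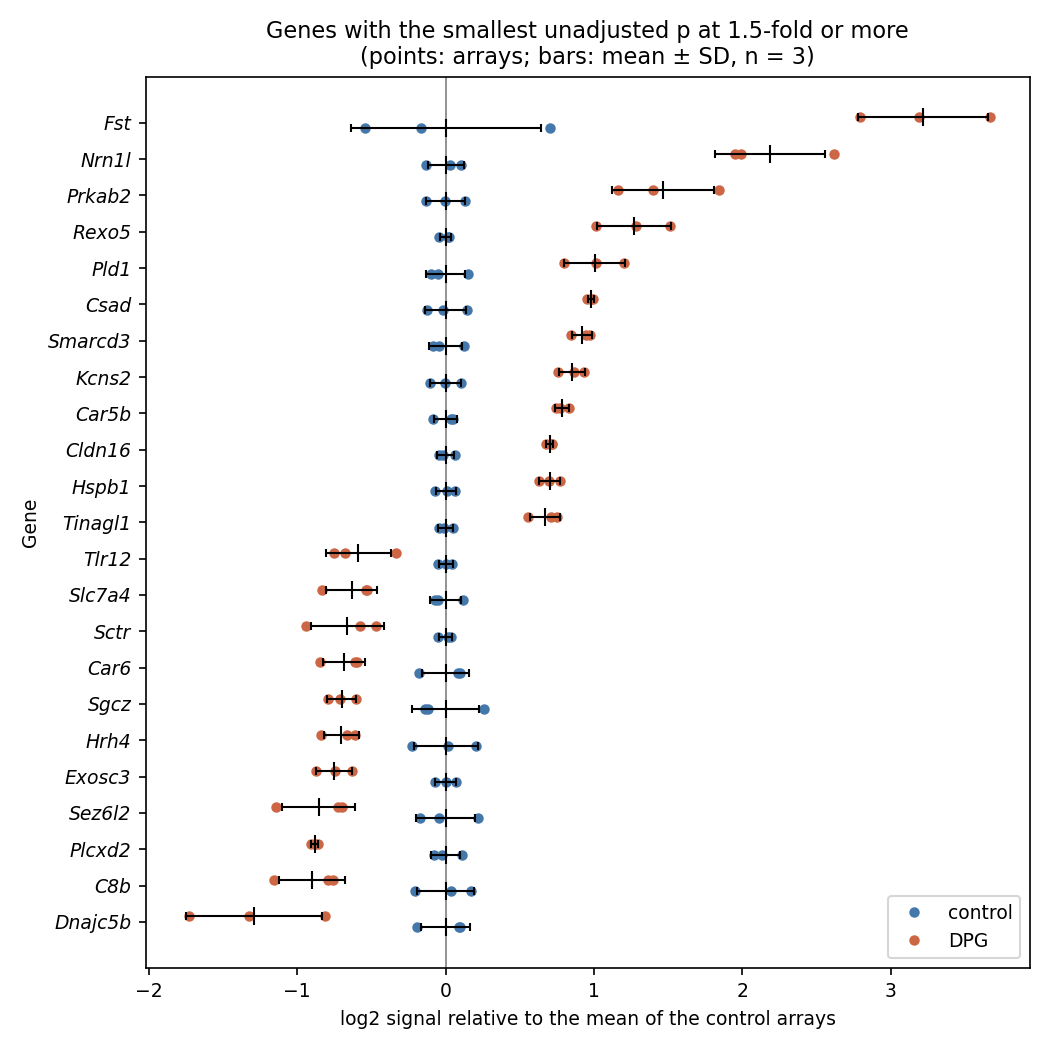
Log2 signal of each array relative to the mean of the 3 control arrays, for the 12 genes higher and 11 genes lower in DPG with the smallest unadjusted p at 1.5-fold or more. Points are arrays and bars are mean ± SD (n = 3); the DPG arrays of Fst lie furthest from control, with a mean log2 difference of 3.22.

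The cell cycle list rose in the DPG rats. The camera test gave an adjusted p = 3.7e-06, and the adjusted p = 0.697 with an estimated correlation. Of 24 measured members, 22 had a log2 fold change above 0, 11 of them at an unadjusted p of 0.05, and 0 passed when adjusted over the list alone. The mean shift of the list in the DPG arrays was 0.13, 0.23 and 0.33 (log2), where the control arrays lay between -0.03 and 0.03. Its members with the smallest p were Nusap1 (log2 fold change 0.47 ± 0.12), Ube2c (0.40 ± 0.11), Aurka (0.27 ± 0.07) and Tk1 (0.25 ± 0.08). Nusap1 and Aurka act in the mitotic spindle, Ube2c in the degradation of mitotic cyclins, and Tk1 in thymidine salvage. Leukocyte and macrophage markers had a median of 0.12 and an adjusted p = 0.352 from camera, with 17 of 21 members above 0. Their mean shift was 0.19 in DPG 1, -0.29 in DPG 2 and 0.39 in DPG 3, and without DPG 2 the list had a median of 0.25 and a camera adjusted p = 1.4e-04.

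The heat shock list rose as well, with 13 of 16 members above 0. This list was fixed in advance as a sign of handling and RNA quality, so its rise need not be a response to DPG. Its camera adjusted p = 0.00135, and adjusted p = 0.697 with an estimated correlation. When adjusted over the list alone, which was not planned, 3 members passed, where 0 did over all genes. These were Hspb1, the lens crystallin and chaperone gene Cryab (1.56 ± 0.35, a 2.95-fold difference), and Serpinh1, a collagen chaperone gene (0.26 ± 0.07). The inducible Hsp70 gene Hspa1a was measured at 1.13 ± 0.35. Cryab and Hspb1 are known to be abundant in the medulla. In the same arrays straight proximal tubule markers, chosen after the lists were examined, had a median of 0.28. The unfolded protein and integrated stress response list did not pass (median 0.14, camera adjusted p = 0.226). Within it Herpud1 had 0.66 ± 0.21, Sdf2l1 0.60 ± 0.12, Creld2 0.57 ± 0.15 and the serine synthesis gene Phgdh -0.35 ± 0.10.

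PPAR-alpha targets and fatty acid oxidation genes fell, with 26 of 32 members below 0. The camera adjusted p = 0.00135, the adjusted p = 0.812 with an estimated correlation, and the adjusted p = 0.0672 with camera when control 2 was left out. Eci1, an enzyme of unsaturated fatty acid oxidation, had -0.42 ± 0.07, and Vnn1, a pantetheinase, had -0.54 ± 0.10. These 2 genes passed when adjusted over the list alone. Cyp4a1, a fatty acid omega-hydroxylase, had -0.50 ± 0.13 and the lipid droplet gene Plin2 -0.40 ± 0.11. Markers of the convoluted proximal tubule, chosen after the lists were examined, lay below 0 in the same arrays, with a median of -0.29 and 8 of 9 members lower. Fatty acid synthesis genes had a median of -0.03 (camera adjusted p = 0.832), and cholesterol synthesis genes one of 0.07 (adjusted p = 0.226). Acss2, an acetyl-CoA synthetase gene, had 0.47 ± 0.13 and Dhcr7, the last step of cholesterol synthesis, 0.26 ± 0.08.

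Among the nephron segments, the podocyte list fell, with 11 of 12 members below 0 (camera adjusted p = 0.0253, and adjusted p = 0.909 with an estimated correlation). Its mean shift was 0.19, -0.12 and -0.07 in controls 1 to 3. In DPG 1 to 3 it was -0.19, -0.21 and -0.07, so the groups overlapped. The nephrin gene Nphs1 had -0.28 ± 0.11, Ptpro -0.22 ± 0.07 and Wt1 -0.19 ± 0.07, and 0 passed over the list alone. The collecting duct and inner medulla list fell too, with 11 of 14 members below 0 (camera adjusted p = 0.0404, and adjusted p = 0.697 with an estimated correlation). The intercalated cell genes Slc26a4, Atp6v1g3 and Atp6v0d2 had -0.40 ± 0.13, -0.30 ± 0.11 and -0.23 ± 0.07, the water channel gene Aqp4 had 0.29 ± 0.09 (its 4 probes from -0.25 to 0.35), and 0 members passed over the list alone. Neither call held with normexp background correction, where the camera adjusted p was 0.123 for podocytes (median -0.09) and 0.0599 for collecting duct. The podocyte adjusted p from camera was 0.221 without control 1 and 0.0616 without DPG 1, and that of the collecting duct was 0.168, 0.130, 0.0559 and 0.214 without control 1, control 3, DPG 1 and DPG 3. In the same arrays markers of the straight proximal tubule had a median of 0.28 and those of the convoluted part one of -0.29, both chosen after the lists were examined.

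Thick ascending limb and distal nephron genes went both ways (10 above and 6 below 0, camera adjusted p = 0.245). Adjusted over the list alone, 5 members passed, where 0 did over all genes. Cldn16, the salt transporter gene Slc12a1 (0.47 ± 0.13) and the uromodulin gene Umod (0.25 ± 0.07) were higher, as was Cldn10 (0.28 ± 0.08), which was named after its values were seen. Trpv5, a calcium channel gene of the distal convoluted and connecting tubule, was lower at -0.42 ± 0.08. Proximal tubule transporter and brush border genes also went both ways, with 13 of 29 above 0 and a camera adjusted p = 0.878. At an unadjusted p of 0.05, 9 of them were higher and 6 lower. Slc22a2 and Slc22a13, which encode organic ion transporters, had 0.70 ± 0.15 and 0.69 ± 0.14, and these 2 passed over the list alone. The 3 probes of Slc22a13 ran from 0.69 to 2.57. Slc6a18 had 0.43 ± 0.12 and Ggt1, a brush border peptidase, 0.40 ± 0.11, while the phosphate transporter gene Slc34a1 had -0.11 ± 0.11. Of the renin-angiotensin, vitamin D and mineral hormone list (median -0.11, camera adjusted p = 0.705), Agt had 0.58 ± 0.16, Vdr -0.22 ± 0.09 and Napsa -0.15 ± 0.06.

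**Figure D2:**
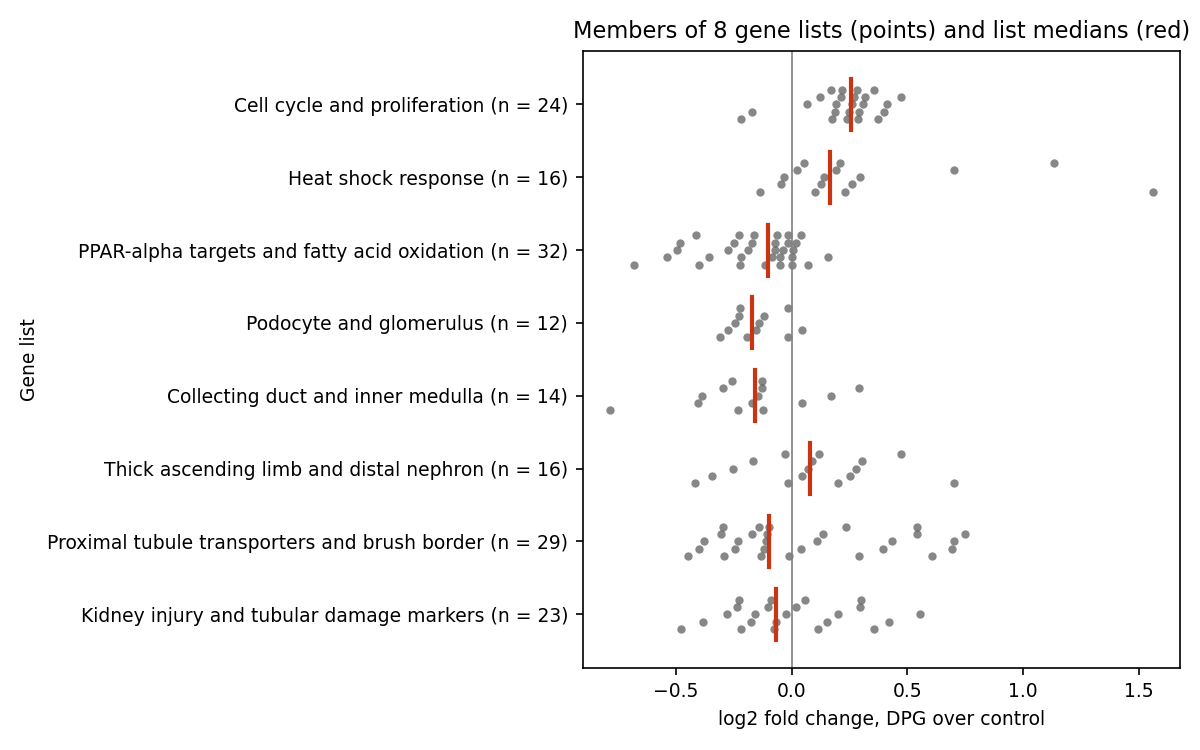
Log2 fold change (DPG over control, horizontal axis) of each measured member of 8 gene lists (points), with the list median as a red line. The medians run from 0.26 for cell cycle genes to -0.17 for podocyte genes, and the proximal tubule members spread to both sides of 0.

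Kidney injury and tubular damage markers did not pass as a list (median -0.07, camera adjusted p = 0.815). Havcr1, which encodes kidney injury molecule 1, had -0.09 ± 0.35, Lcn2 0.20 ± 0.34, Clu -0.22 ± 0.29, Spp1 0.30 ± 0.20 and Timp1 0.02 ± 0.08. The members with the smallest p were Tff3 (0.56 ± 0.16), Anxa2 (0.36 ± 0.10), Krt8 (-0.28 ± 0.08) and Icam1 (-0.24 ± 0.09). The p53 target list had a median of -0.04 and a camera adjusted p = 0.680, and Cdkn1a had -0.18 ± 0.10, with a second probe at 0.52.

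The alcohol, aldehyde and glycol oxidation list, which also holds other enzymes such as Hagh, had a median of -0.06 and a camera adjusted p = 0.182. At an unadjusted p of 0.05, 7 members were lower and 2 higher. Adh1c, an alcohol dehydrogenase gene, had -0.50 ± 0.18, Aldh1a1 -0.40 ± 0.13, Cyp2e1 -0.34 ± 0.12, Sord -0.23 ± 0.08, Hagh 0.25 ± 0.07 and Aldh2 0.05 ± 0.06. Xenobiotic metabolism genes had a median of -0.08 (camera adjusted p = 0.687), with Ahrr at -0.54 ± 0.16, Ces1d at -0.37 ± 0.12, Cyp2d4 at 0.37 ± 0.13 and the epoxide hydrolase gene Ephx1 at -0.31 ± 0.08. Targets of NRF2, the transcription factor of the oxidative stress response, had a median of 0.01 (camera adjusted p = 0.690). Within that list Osgin1 had 0.79 ± 0.19, Me1 0.50 ± 0.17, the glutathione synthesis gene Gclc 0.42 ± 0.10 and Abcc4 -0.30 ± 0.10.

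Osmolyte and tonicity genes had a median of 0.11 (camera adjusted p = 0.308), with the betaine transporter gene Slc6a12 at 0.46 ± 0.11. Gluconeogenesis and glucose genes had a median of 0.01 (camera adjusted p = 0.815), with Hk1 at 0.30 ± 0.09, Glul at 0.24 ± 0.07, Khk at 0.22 ± 0.06 and Pck1 at -0.29 ± 0.09. Hypoxia targets had a median of -0.01 (camera adjusted p = 0.878), and the glucose transporter gene Slc2a1 (0.45 ± 0.08) passed over the list alone. Glucocorticoid targets and metallothioneins had a median of -0.02 (camera adjusted p = 0.832), and Fkbp5 (0.74 ± 0.13), a glucocorticoid-induced chaperone gene, passed over the list alone. Acute phase and complement genes had a median of -0.04 (camera adjusted p = 0.245), and the haptoglobin gene Hp (-0.55 ± 0.09) passed over the list alone. The camera adjusted p was 0.147 for cytosolic ribosomal proteins (median 0.05), 0.366 for immediate early genes (0.12), 0.502 for interferon response genes (0.03), 0.687 for circadian clock genes (0.02) and 0.878 for the mitochondrial respiratory chain (-0.01).

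Markers of other cell types gave camera adjusted p = 0.878 for endothelium (median -0.04), 0.832 for fibroblasts and smooth muscle (0.03) and 0.832 for red blood cells (0.05). Adipocyte markers had a median of 0.12 (camera adjusted p = 0.832) and a mean shift of 0.50, 0.21 and 0.48 in the DPG arrays, with Fabp4 at 1.89 ± 0.70 and Adipoq at -0.45 ± 0.14. Adrenal cortex markers had a median of 0.23 (camera adjusted p = 0.690). Of its 5 members Cyp17a1 (-0.41 ± 0.07) and Cyp11b3 (0.99 ± 0.23) passed over the list alone, in opposite directions. The Cyp11b3 probe was well above background on 1 of 3 control arrays, and its second probe read 0.21. Median, mean and camera direction differed in sign for the proximal tubule, endothelium, hypoxia, glucocorticoid, respiratory chain, circadian clock and renin-angiotensin lists. All control arrays lay on 1 slide and in 1 scan run, and all DPG arrays on another, so slide or scan and group cannot be told apart.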

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

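The count of features past an unadjusted p of 0.05 was listed with its alternatives only after the data were seen. The adjusted count was 0 in each alternative that kept all 6 arrays, and ranged from 0 to 1 with an animal left out. It was 1 without control 2 and without DPG 2, where the cause was not tested. The count at an unadjusted p of 0.01 and 1.5-fold was 198 with normexp, against 338, and ranged from 275 to 525 with an animal left out, with 525 without DPG 3. The count at an unadjusted p of 0.05, against 3669, ranged from 2569 without DPG 1 to 4493 with normexp, and with every probe on its own, which counts probes and not features, it was 5008. The number of lists past the camera threshold was 3 with normexp, 0 with an estimated correlation and 0 with fry's directional test. It ranged from 3 (without control 1) to 8 (without DPG 2) with an animal left out. Fry's mixed test, which ignores direction and does not weigh a list against other genes, passed 16 of 32 lists. The cell cycle and heat shock lists passed in each camera run with the preset correlation, and with fry both had an adjusted p = 0.126, and with the estimated correlation 0.697. The PPAR-alpha list had 0.812 with the estimated correlation, 0.178 with fry, and 0.000174 to 0.0672 with an animal left out, the highest without control 2. The podocyte list had 0.123 with normexp, 0.909 with the estimated correlation, 0.286 with fry, and 0.0106 to 0.221 with an animal left out. The collecting duct list had 0.0599 with normexp, 0.0779 with probes well above background on all arrays, 0.697 with the estimated correlation, 0.178 with fry, and 0.0106 to 0.214 with an animal left out. The cause of these changes was not tested. The trend and the array weights do not enter camera and leave its values as they are by construction. Replicate numbers did not pair the animals, as same-numbered arrays had correlations of their deviations of -0.02, -0.09 and -0.07. With the replicate block the counts were 0, 315 and 2987 features and 5 lists. The leukocyte list had a camera adjusted p = 1.4e-04 without DPG 2, and 9 of 539 alternative values of lists that had not passed did so. Of 2821 alternative values of the named genes, 19 changed sign and 0 passed the adjusted threshold. All 431 for the 24 leading genes kept their sign. These genes were chosen by smallest p and their groups did not overlap, so the choice itself made a change of sign unlikely. Median scaling moved the median of all features by 0.01 (log2). A slide block was not run.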

Other observations

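The tests of straight and convoluted tubule markers, second probes, array position and signal-matched lists were set before their values were seen, and so were the split counts of 1.5-fold features and of lists. The other tests here, and the gene families, were chosen after the result was seen. Proximal tubule markers outside the fixed lists parted by segment. Of 15 measured markers of the straight part, which runs into the outer medulla, 12 had a log2 fold change above 0, with a median of 0.28. Of 9 measured markers of the convoluted part in the outer cortex, 8 lay below 0, with a median of -0.29. Both lists came from general knowledge and were written down after the fixed lists had been examined. Markers of the straight part included Slc22a24 (1.37 ± 0.22), Slc7a13 (0.78 ± 0.16), the meprin genes Mep1b (0.54 ± 0.18) and Mep1a (0.39 ± 0.09), and the peptide transporter gene Slc15a2 (0.50 ± 0.20). Slc5a8 went the other way at -0.39 ± 0.22. In the convoluted part Slc15a1 had -0.35 ± 0.15, the creatine synthesis gene Gatm -0.35 ± 0.15 and Slc5a12 -0.29 ± 0.08. All 24 markers passed the background filter in these cortex samples, and no other zone of the kidney was measured for comparison. None of these markers passed the limma adjusted threshold, and those named here were chosen after their values were seen. In each DPG array the straight list shifted up (0.31, 0.33 and 0.23, against -0.14 to 0.09 in controls) and the convoluted list down (-0.21, -0.29 and -0.22, against -0.06 to 0.07). Camera gave the straight list an unadjusted p = 0.00151 and the convoluted list 8.0e-05, and with an estimated correlation p = 0.0645 and p = 0.0294.

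Of 205 families of genes that share a symbol stem, 0 passed camera after adjustment. The organic anion transporter family Slco had a median of 0.60, with 8 of 11 members above 0, and the annexins (Anxa) had 9 of 9 members above 0 with a median of 0.16. The replication licensing family Mcm had 7 of 8 above 0, and the keratin-associated family Krtap 2 of 11. Each of these 4 had an adjusted p = 0.122 from camera. Of the 338 features past an unadjusted p of 0.01 and 1.5-fold, 199 had no gene symbol.

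Straight tubule markers lay higher in DPG, while the podocyte and collecting duct lists lay lower (adjusted p = 0.909 and 0.697 with an estimated correlation). A deeper cut of the cortex in the DPG animals stays undecided. It needs straight tubule markers above convoluted ones, and the medians differed by 0.57 (log2, from 0.42 to 0.69 over 8 other settings), but the straight markers are part of the pattern itself and an effect of DPG on that segment would give the same. Inner medulla in the samples was taken to need the collecting duct and inner medulla list higher, while its median was -0.16. That explanation stays undecided too, since the list's fall did not pass camera with an estimated correlation (adjusted p = 0.697). The list is also part of the pattern itself, and it holds intercalated cell genes such as Slc26a4 (-0.40) beside Aqp4 (0.29). Its direction therefore cannot decide on inner medulla. A direct effect of DPG on these segments stays open as well, since no section or image bears on it, and Cryab and Hspb1, known to be abundant in the medulla, could follow such a cut.

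Unadjusted small p-values were more frequent than chance gives. An effect of single spots or probes is argued against by second probes, but only for the 957 of these 3669 features that had one. Of these second probes 87.5% had the same sign (837 of 957, 95% exact binomial interval 85.2% to 89.5%). The share was 57.5% among 2951 features with much larger unadjusted p. Features with a single probe were not tested in this way. Array position explained 4.74% of the variance of the log2 fold changes (95% interval 3.40% to 6.29%), which left a gradient undecided, but 3293 features still passed an unadjusted p of 0.05 once each array's block medians were removed. With 0 slides holding both groups, slide or scan and treatment cannot be told apart. The splits of the 6 arrays number 10, too few for a share under 0.05: the real split and the highest other gave 3669 and 1938 features at an unadjusted p of 0.05 (1 split as large), 338 and 186 at 0.01 with 1.5-fold (1 split), 0 and 1 at an adjusted p of 0.05 (10 splits), and 5 and 8 lists (5 splits).

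The cell cycle list rose (adjusted p = 0.697 with an estimated correlation), and a bias that depends on signal is argued against by its median, which lay at percentile 100 of 10000 random lists matched on mean signal. More leukocytes in the tissue stay undecided: the leukocyte list's median lay 0.13 below that of the cell cycle list (permutation p = 0.00464 across genes, which are not independent replicates), but the difference was -0.01 (permutation p = 0.593) without DPG 2 and 0.05 (permutation p = 0.188) without control 2. Among the other splits of the arrays the smallest adjusted p values of the cell cycle list from camera were 8.1e-05, 9.4e-04 and 0.00185, against 3.7e-06. Chance, slide or scan, leukocytes and a response to DPG stay open.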
